A study of Mus musculus with 12 samples.

How the data were processed

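RNA was sequenced from 12 C57BL/6 mouse samples in 4 groups of 3. Hippocampal microglia, the resident macrophages of the brain, were taken at 3 or 24 months of age, and whole hippocampus at 6 or 18 months. Per the labels' protocols, RNA was isolated with Trizol, 5 ng of total RNA was reverse transcribed from an oligo-dT primer with template switching, the cDNA was amplified in 12 PCR cycles, and libraries were made by tagmentation. The labels name neither molecular identifiers nor a kit that keeps strand, and they do not say how the microglia were isolated. Reads from a gene and an antisense partner could therefore not be told apart.

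The submitters' processing notes name kallisto, DESeq and DESeq2 without versions, and the builds GRCm39 and mm10 without saying which file used which. For the microglia, the authors deposited TPM values, estimated counts and average transcript lengths per gene and sample, per the file headers; the column names are those tximport writes when it sums transcripts to genes. The TPM columns were not used for tests. For each tissue the authors also deposited a comparison table that gives, per the file headers, each gene's normalized counts (a signal scaled between samples), a base mean, a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value. In the microglia, the authors' normalized count equalled the rounded estimated count divided by the gene's relative length and by 1 size factor per library for 100% of the genes checked, within 0.1 percent. Genes with low normalized counts were left out of this check. Log2 values in the deposited hippocampus table are 6 over 18 months, judged from its own sample columns, and were turned here to 18 minus 6 months. Every other log2 change is likewise older minus younger.

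Estimated counts of the microglia were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the 6 microglia samples, with TMM scaling and the filterByExpr filter, which left 10663 genes. Levels are CPM on the TMM-scaled library size. The hippocampus table used here holds normalized counts and no counts, so the planned fallback was used: limma's moderated test with a mean trend (limma 3.58.1) on log2(normalized count + 1), for the 13491 genes with a value of at least 1 in at least 3 samples. Fold changes on that scale understate the change of low genes. Adjusted p-values are Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Tests were two-sided.

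A total of 41 gene lists (microglial states, stress, immune, metabolic and translation genes, and markers of other brain and blood cells) was fixed before the data were examined. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry, which asks whether a list's own genes move in a common direction, were alternatives. For homeostatic, interferon, MHC class I and reactive astrocyte genes in microglia the estimate was 0.0039, -0.016, 0.0091 and -0.052, not above the preset. A higher correlation therefore does not explain why the calls of these lists were lost with that setting. Counts of list members "adjusted over the list alone" use the same gene-level p-values adjusted within the list. Genes are named by a rule fixed at the same time: 21 genes per comparison whatever their result, up to 8 genes per direction with the greatest change among calls whose groups do not overlap and whose mean lies in the upper part of tested genes, and up to 4 members with the smallest adjusted p of each list described. As edgeR and limma called no gene, the second part of the rule was filled from the authors' deposited tables. Any other gene named, such as Trem2, Tyrobp and Nfkbia, was chosen after its values were seen. Some genes that the rule takes are not reported here.

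The microglia libraries held 8072855 to 14226478 estimated counts. The entry without a gene name, which held 0.0546% to 0.0771% of the counts, was left out. Every sample column was used (0 matched no sample). In the hippocampus, the blank entry held 0.0233% to 0.0335% of the signal. Symbols that a spreadsheet had turned into dates (27 in the microglia file, 22 in the hippocampus file) were kept as they stand and not named, and names that occur more than once (4 and 2 entries) were kept apart. The hippocampus columns summed to 974372 to 1002839 normalized counts. Steps of genes seen in a single library put the depth at roughly 548473 to 1945335 reads, but only 23.5% to 50.3% of the low values were whole multiples of such a step (tolerance 0.1), so reads were not recovered and no interval was given. Where a microglia group was at 0, a fold was given against a floor of 3 counts over the group. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Y-linked Ddx3y was counted in all 12 samples. Genome positions are from GENCODE M21 on GRCm38 (mm10, 1 of the 2 builds the submitters' processing notes name) and were not used in any test.

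The procedures were tested on simulated data with 200 changed genes drawn from the real means and depths. With the microglia's estimated spread, edgeR recovered 0 of 67 genes changed 2-fold, 7.46% of 67 changed 4-fold and 25.8% of 66 changed 8-fold with 3 false calls among 10025 genes; DESeq2 recovered 4.48%, 50.7% and 60.6% with 93 false calls among 10663. In the simulated hippocampus (13680 genes), limma recovered 40.3% of 67 genes changed 2-fold and 76.1% of 67 changed 4-fold with 3 false calls. In both tissues the changed genes were drawn from the better expressed ones only. In the hippocampus each gene was given the median spread of genes of like level. Simulated hippocampus values were whole multiples of a step, which many low real values were not. Recovery in the real data may therefore be lower. Camera recovered 3 of 3 raised lists in each tissue with 0 false lists, but simulated genes were drawn independently of each other. In the real data genes of a list can be correlated (estimated correlation 0.72 for mitochondrially encoded mRNAs in microglia). The simulation therefore cannot show how often camera calls false lists there.

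Alternatives planned before the data were examined were DESeq2 size factors or quantile scaling, the DESeq2 Wald test (DESeq2 1.42.0), limma without the trend, no low-value filter, a pseudocount of 0.1, an adjusted p under 0.01, an added 2-fold minimum, each replicate left out, the replicate number as a block, and the authors' own calls with and without a base mean of at least 10. Gene length offsets, DESeq2 with the deposited gene lengths, library weights and 2 sets of left-out libraries were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.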

Results

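The data are 6 libraries of hippocampal microglia (3 from mice of 3 months, 3 from mice of 24 months) and 6 of whole hippocampus (3 at 6 months, 3 at 18 months). The design compares young with old microglia and mature with aged hippocampus. The microglia libraries held 8072855 to 14226478 estimated counts and 11789 to 13839 genes with a count. Of 7832 genes with a mean above 10 CPM, 394 (5.03%) had no count in 3 month replicate 1, 188 (2.40%) in 24 month replicate 1 and 25 to 60 in each other library. Microglia libraries did not group cleanly by age. On log2 values, 24 month replicate 3 had a Pearson r of 0.820 and 0.824 with 3 month replicates 2 and 3. With 24 month replicates 1 and 2 its r was 0.678 and 0.782. The labels do not say that the samples of a group came from separate mice, so p-values measure the spread between these samples.

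Microglia of 24 months held more mRNA of genes that mark activated, disease-associated microglia, and slightly less of homeostatic genes. Apoe, the lipid carrier of glia (chromosome 7, 19696109 to 19699188), averaged 811.6 ± 159.0 CPM (SD, n = 3) at 3 months and 3743.1 ± 1031.8 CPM (SD, n = 3) at 24 months. Its log2 change was 2.21 ± 0.26 (SE), and the 3 old libraries, at 2868.3 to 4880.9 CPM, all lay above the young ones. Spp1, the secreted glycoprotein osteopontin (chromosome 5, 104435118 to 104441050), went from 1.61 ± 2.28 to 184.9 ± 78.5 CPM (SD, n = 3 each; log2 change 6.95 ± 1.19, SE). Lpl, which hydrolyses triglycerides of lipoproteins, had a log2 change of 4.42 ± 0.96 (SE). Gpnmb, a transmembrane glycoprotein of lipid-laden phagocytes, was at 0 in the 3 young libraries and at 11.3 ± 10.2 CPM (SD, n = 3) at 24 months, with 23.1 CPM in 24 month replicate 1 and 6.05 and 4.75 CPM in the others. That is at least 132-fold higher against a floor of 3 counts over the young group, and at least 65.3-fold without 24 month replicate 1.

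The list of disease-associated genes rose as a group: 21 of its 26 tested members had a higher mean at 24 months, with a median log2 change of 0.57 (camera, adjusted p = 5.43e-06). The call was lost with a correlation estimated from the data (adjusted p = 0.256 with an estimated correlation) and with fry (adjusted p = 0.0850). With p-values adjusted over the list alone, 8 members rose and 0 fell. In 12 members every old library lay above every young one and in 2 below, where chance separates the groups of about 10% of genes. Cst7, a cysteine protease inhibitor, had a log2 change of 1.85 ± 0.63 (SE), Clec7a, a fungal glucan receptor, of 1.97 ± 0.57, Axl, a receptor for dying cells, of 4.05 ± 1.18, and Lgals3, a galactoside-binding lectin, of 3.64 ± 1.41. Itgax, an integrin of dendritic cells and activated microglia, was at 45.8 CPM in 3 month replicate 1, at 0.125 and 0.0681 CPM in the other young libraries and at 12.5 to 28.6 CPM in the old ones (log2 change 0.59 ± 1.92, SE). Trem2 and Tyrobp, the receptor and adaptor that signal lipid sensing, had changes of -0.37 ± 0.18 and -0.50 ± 0.31 (SE). None of these genes passed over all genes; adjusted over the list alone, Clec7a and Axl passed (0.0323 each), while Cst7 (0.0560), Lgals3 (0.0875), Trem2 (0.158) and Tyrobp (0.226) did not.

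Homeostatic genes fell together: 20 of 23 tested members had a lower mean at 24 months, with a median log2 change of -0.28 (camera, adjusted p = 5.43e-06; adjusted p = 0.190 with an estimated correlation). No member passed with p-values adjusted over the list alone (0 of 23), 5 had an unadjusted p under 0.05, and in 7 every old library lay below every young one (chance gives 10% in either direction). Csf1r, the receptor that keeps microglia alive, averaged 12773.5 ± 562.2 CPM at 3 months and 8887.7 ± 1371.7 CPM at 24 months (SD, n = 3 each; log2 change -0.52 ± 0.17, SE). The log2 changes were -0.54 ± 0.22 (SE) for Tmem119, a surface marker of resident microglia, -0.82 ± 0.22 for Ltc4s, a leukotriene synthase, -0.49 ± 0.17 for Fcrls, an Fc receptor-like protein, and -0.59 ± 0.24 for Selplg, a selectin ligand. With 24 month replicate 3 left out, the falls were larger for Tmem119 (-0.81), Selplg (-0.90) and Csf1r (-0.68). In that library the list score lay below the young mean by 67.4% of the fall in 24 month replicates 1 and 2. The purinergic receptor P2ry12 (0.03 ± 0.17, SE), the fractalkine receptor Cx3cr1 (-0.15 ± 0.18) and the TGF-beta receptor Tgfbr1 (-0.09 ± 0.18) differed by less than their errors. Both this list and the disease-associated one kept their call with each replicate left out.

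**Figure D1:**
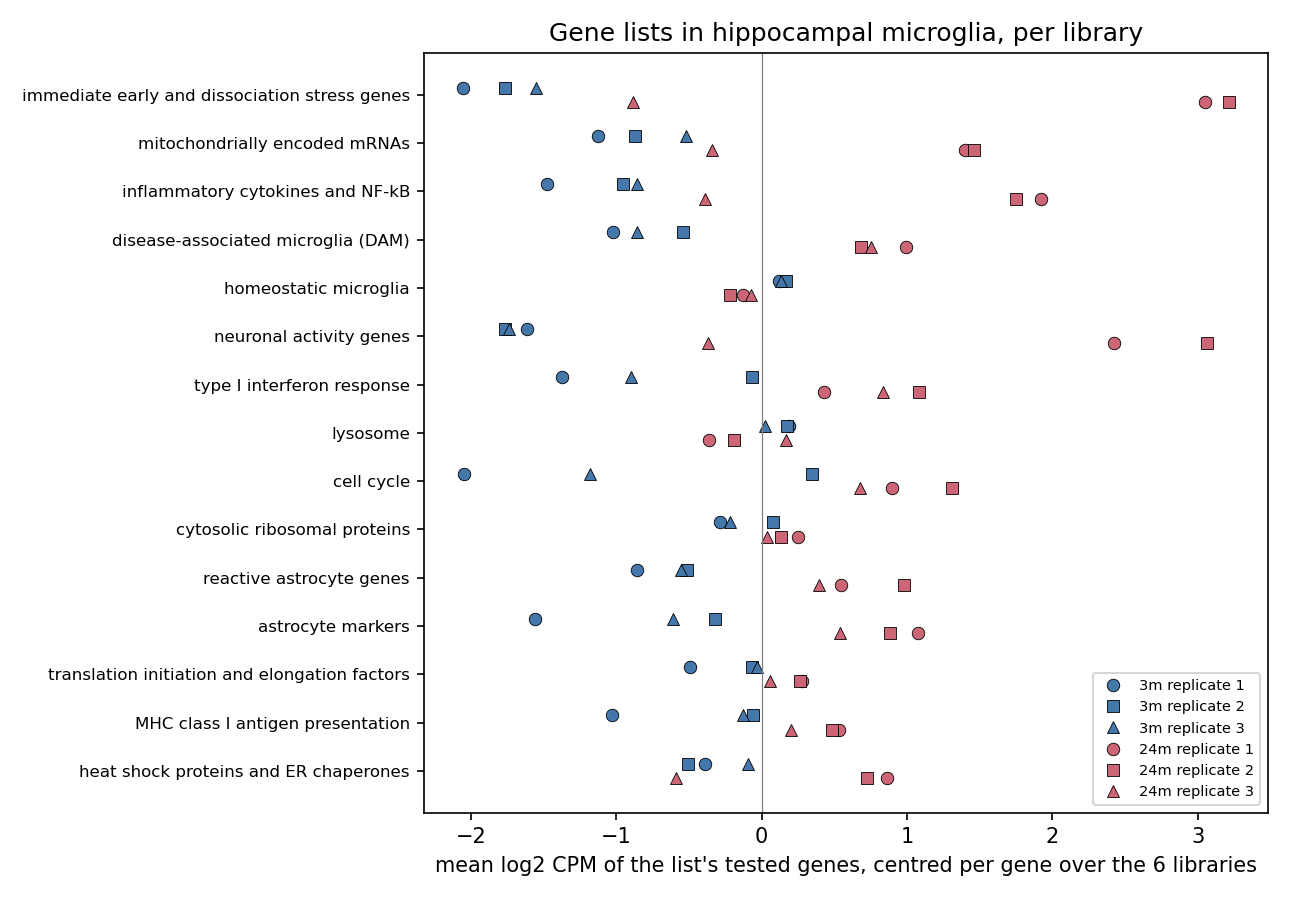
Score of each gene list with a camera adjusted p under 0.05 in the 6 microglia libraries: the mean log2 CPM of its tested genes (x axis), centred per gene over the libraries. Blue marks are 3 months, red marks 24 months, and the shape gives the replicate number; 24 month replicates 1 and 2 reach 3.05 and 3.22 for immediate early genes while 24 month replicate 3 is at -0.89, and all 3 lie together for disease-associated genes (0.68 to 0.99).

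Genes of antigen presentation and of the interferon response were also higher in the old microglia. H2-K1, an MHC class I heavy chain (chromosome 17, 33996017 to 34000347), went from 476.8 ± 37.1 to 1593.4 ± 682.4 CPM (SD, n = 3 each; log2 change 1.74 ± 0.34, SE), and its relative H2-D1 changed by 0.88 ± 0.18. Without 24 month replicate 3 the change of H2-K1 was 2.04, so that library rose less than the other old ones. H2-K1, H2-D1 and H2-Q6 (log2 change 4.10 ± 1.30, SE) have near-identical stretches, so the split of reads among them is uncertain. B2m, the light chain they share, had a log2 change of 0.60 ± 0.17 (SE). The MHC class I list rose (13 of 20 members with a higher mean, median 0.26, camera adjusted p = 0.0212; adjusted p = 0.256 with an estimated correlation), with 2 members, H2-K1 and H2-D1, past the threshold when adjusted over the list alone. Its adjusted p was 0.154 without 24 month replicate 1 and 0.0761 without 3 month replicate 3. The score of the class I list rose in 24 month replicate 3 by 66.1% of the rise in 24 month replicates 1 and 2. Type I interferon genes rose (21 of 25 members with a higher mean, median 1.32, adjusted p = 3.41e-04; adjusted p = 0.190 with an estimated correlation; 0 past the threshold adjusted over the list alone, the smallest at 0.102). Their lead members were Ifi27l2a, an interferon-induced mitochondrial protein (log2 change 4.79 ± 1.31, SE), Trim30a, a ubiquitin ligase (1.49 ± 0.42), Slfn2, a Schlafen growth regulator (1.78 ± 0.57), and Ifit3, which binds foreign RNA (2.89 ± 1.06). The interferon call was lost without 3 month replicate 3 (adjusted p = 0.0583). For the interferon list the rise in 24 month replicate 3 was 105% of that in 24 month replicates 1 and 2. Ifitm3, a membrane protein that blocks viral entry, showed no change beyond its error (-0.01 ± 0.95, SE), but was at 1.51 without 3 month replicate 1. Cd74, the invariant chain of MHC class II, was at 21.0 ± 10.1 and 74.5 ± 5.22 CPM (SD, n = 3 each; log2 change 1.83 ± 0.52, SE), while the class II list as a whole did not pass (adjusted p = 0.117) but did without 3 month replicate 1 (0.00801) and with replicate 1 of both ages left out (0.00181).

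Immediate early and inflammatory genes rose, carried mostly by 2 of the 3 old libraries. Fos, a transcription factor switched on within minutes of a stimulus (chromosome 12, 85473890 to 85477273), reached 4190.4 and 4261.3 CPM in 24 month replicates 1 and 2 but 48.5 CPM in 24 month replicate 3, against 2.99 to 28.2 CPM at 3 months. Tnf, the inflammatory cytokine, stood at 644.6 and 466.5 CPM in those 2 libraries, 10.2 CPM in 24 month replicate 3 and 0.597 to 1.97 CPM at 3 months. Egr1 had a log2 change of 7.34 ± 1.65 (SE), Klf2 of 8.80 ± 1.47 and Ier2 of 5.03 ± 1.02, all transcription regulators of the first response to stimulation. All 23 tested members of the immediate early and dissociation stress list had a higher mean at 24 months, and 19 rose with p-values adjusted over the list alone (median 3.38, camera adjusted p = 8.59e-14; adjusted p = 0.256 with an estimated correlation). Among inflammatory cytokines and NF-kB genes, 19 of 22 had a higher mean and 12 rose when adjusted over the list alone (median 1.88, adjusted p = 1.25e-09; adjusted p = 0.256 with an estimated correlation). These include the chemokines Ccl3 (4.37 ± 0.94, SE) and Ccl4 (3.97 ± 0.84) and Il1rn, the antagonist of the interleukin 1 receptor (6.43 ± 1.07). Unlike Tnf, Il1rn was high in each old library, at 19.9, 30.2 and 36.4 CPM. Il1b, an inflammasome product, had a log2 change of 4.02 ± 2.07 (SE) and was at 1.71 CPM in 24 month replicate 3. In 24 month replicate 3 the list score rose over the young mean by 18.4% of the rise in 24 month replicates 1 and 2 for immediate early genes and by 24.1% for cytokine genes.

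**Figure D2:**
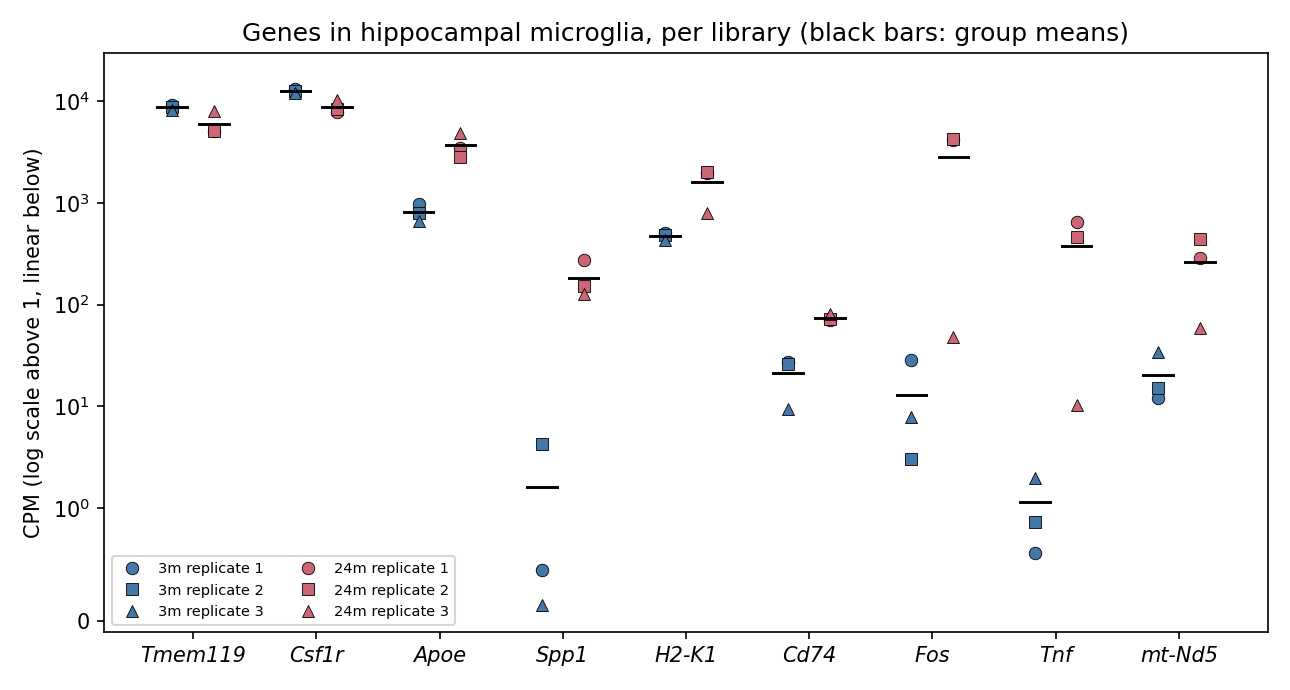
CPM of 9 genes in the 6 microglia libraries (y axis, log scale above 1 and linear below), with black bars at the mean of each age. Apoe and Cd74 are high in all 3 old libraries (Apoe 2868.3 to 4880.9 CPM), while Fos is at 4190.4 and 4261.3 CPM in 24 month replicates 1 and 2 and at 48.5 CPM in 24 month replicate 3.

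The same 2 libraries stood apart in mitochondrial mRNA. Transcripts encoded by the mitochondrial genome made up 0.883% and 0.888% of the counts in 24 month replicates 1 and 2, 0.326% in 24 month replicate 3 and 0.249% to 0.293% at 3 months. All 13 such mRNAs had a higher mean at 24 months (median log2 change 1.65, camera adjusted p = 4.13e-10; adjusted p = 0.256 with an estimated correlation), and 10 rose when adjusted over the list alone. Among them mt-Nd5, a subunit of respiratory complex I, had a log2 change of 3.67 ± 0.76 (SE), and the oxidase subunits mt-Co2 and mt-Co3 had 1.65 ± 0.43 and 1.32 ± 0.34. Nuclear genes of oxidative phosphorylation did not pass (median -0.10, adjusted p = 0.280) but passed as lower without 24 month replicate 1 (0.01995) and with replicate 1 of both ages left out (0.0438). In 24 month replicate 3 the score of the mitochondrial list rose by 21.8% of the rise in the other old libraries.

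A further 8 lists changed. Lysosomal genes fell (28 of 37 members with a lower mean, median -0.20, adjusted p = 7.51e-04; adjusted p = 0.523 with an estimated correlation; 0 past the threshold adjusted over the list alone). They were led by Grn, the progranulin gene (-0.56 ± 0.18, SE), and Lgmn, a lysosomal protease (-0.52 ± 0.23). In 24 month replicate 3, Lgmn (11632.3 CPM) lay within the young range, and the list's median was 0.0872 in that library against the young ones. Heat shock proteins and chaperones of the endoplasmic reticulum rose (16 of 23 higher, median 0.45, adjusted p = 0.0282; adjusted p = 0.535 with an estimated correlation; 0 past the threshold adjusted over the list alone), led by Herpud1 (1.05 ± 0.33, SE) and Dnajb1 (2.43 ± 0.77). That call was lost without 24 month replicate 1 (adjusted p = 0.342), 24 month replicate 2 (0.184) or 3 month replicate 2 (0.201). In 24 month replicate 3 alone against the young libraries the median was -0.23. Cell cycle genes rose (16 of 22 higher, median 1.37, adjusted p = 0.00116; adjusted p = 0.256 with an estimated correlation; 0 past the threshold adjusted over the list alone). That call was lost with replicate 1 of both ages left out (adjusted p = 0.124), a setting chosen after seeing the data, as were those of lysosomal genes (0.231), MHC class I (0.186), translation factors (0.231) and heat shock proteins (0.256). Cdc20, an activator of mitotic exit, was at 0 in the young libraries and at least 250-fold higher at 24 months, with 50.8 CPM in 24 month replicate 1 and 5.04 and 8.64 CPM in the others (at least 83.7-fold without 24 month replicate 1). The lists of ribosomal proteins (58 of 78 higher, median 0.28, adjusted p = 0.00116; adjusted p = 0.522 with an estimated correlation) and of translation factors (22 of 33 higher, median 0.29, adjusted p = 0.0164; adjusted p = 0.256 with an estimated correlation) rose, with 0 members of each past the threshold adjusted over the list alone. The ribosomal call was lost without 3 month replicate 3 (adjusted p = 0.317) or 24 month replicate 1 (0.154). The translation call was lost without 24 month replicate 1 (adjusted p = 0.154), 3 month replicate 3 (0.0761) or 3 month replicate 1 (0.0529). Ribosomal protein genes share reads with many pseudogenes and are uncertain.

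Of lists named for other cells, 3 rose. The neuronal activity list (6 of 7 higher, 4 adjusted over the list alone, median 3.19, adjusted p = 2.53e-04; adjusted p = 0.263 with an estimated correlation) was led by Fos, Egr1, Egr2 and Junb, which also belong to the immediate early list. The reactive astrocyte list (10 of 11 higher, 1 adjusted over the list alone, median 0.57, adjusted p = 0.00809; adjusted p = 0.256 with an estimated correlation) was led by H2-D1, the MHC class I chain. The astrocyte marker list rose (7 of 9 higher, 0 adjusted over the list alone, median 0.94, adjusted p = 0.0125; adjusted p = 0.256 with an estimated correlation). It holds the low transcript Mt3, a metal-binding protein (0.295 ± 0.398 and 5.66 ± 1.25 CPM, SD, n = 3 each), and the more abundant Slc1a3, a glutamate transporter (193.3 ± 72.9 and 322.2 ± 53.7 CPM, SD, n = 3 each). Of the 20 listed astrocyte markers only 9 were tested, and several others were nearly absent. Aqp4 had 29 estimated counts in 3 month replicate 3 and 0 elsewhere. Gja1 had 34 in 24 month replicate 2 and 0 elsewhere. Markers of monocytes and neutrophils summed to 3523.7 CPM in 24 month replicate 1 and to 570.3 to 720.3 CPM in the other 5 libraries. The excess lay in neutrophil genes outside the tested set, such as S100a8 with 12179 estimated counts in 24 month replicate 1 and 1 to 213 in the others, so the list test does not cover it. The same library alone held smooth muscle transcripts outside the tested set, Acta2 with 2031 estimated counts against 1 to 8 in the others and Tagln with 608 against 0. Pan-neuronal markers (adjusted p = 0.553), myelin genes (0.970) and endothelial markers (0.970) did not pass. Of the 20 endothelial markers only 7 were tested. Outside the tested set, 24 month replicate 2 held Kdr with 347 estimated counts against 0 to 44 in the others. Cldn5 had 148 there against 0 to 1. Slco1a4 had 84 and Slco1c1 67 in that library against 0 in the others, while Ly6c1 was highest in 3 month replicate 1 (93 against 23). The mural markers Rgs5 (266 against 0 to 82) and Vtn (118 against 0 to 1) were also highest in 24 month replicate 2. Pdgfrb, Kcnj8 and Higd1b, mural markers too, had 0 in every library. All endothelial markers together summed to 835.7 CPM in 24 month replicate 2 and to 787.0 to 1233.6 CPM in the others. That sum lay mostly in the tested markers, so it cannot show an excess of the untested ones. The senescence list did not pass (adjusted p = 0.221) but did without 24 month replicate 3 (0.0272). Its member Cdkn1a, the cell cycle inhibitor p21, had a log2 change of 3.20 ± 0.78 (SE) with 498.8, 322.6 and 45.8 CPM in the old libraries. TGF-beta signalling (adjusted p = 0.970) and lipid storage (adjusted p = 0.970) did not pass; Tgfb1 was at 0.834 ± 0.692 and 7.10 ± 3.14 CPM (SD, n = 3 each; log2 change 3.07 ± 1.38, SE).

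Gene by gene, edgeR's quasi-likelihood test called 0 of 10663 genes higher and 0 lower in old microglia, with the smallest adjusted p, 0.410, at Apoe. At an unadjusted p under 0.05 there were 375 genes higher and 215 lower, 590 together where 533 were due by chance. The spread was high (common dispersion 0.859), and groups did not overlap for 13.4% of genes, where chance gives 10%. DESeq2's Wald test on the same counts called 194 genes higher and 57 lower. The authors' deposited table, made with DESeq2 and gene lengths, lists 186 higher and 57 lower at an adjusted p under 0.05, and all 243 were called with the same sign when that fit was rebuilt from the deposited counts and lengths. With 24 month replicate 3 left out, edgeR called 50 genes higher and 5 lower, among them Nfkbia, Klf6, Tnf, Jun and H2-K1 as higher and Csf1r and Tmem119 as lower; with any other replicate left out it called 0. With 1 replicate left out, the rebuilt DESeq2 fit kept 90 to 203 of the 243 calls. By the authors' deposited table, the greatest rises among well expressed genes (mean in the upper part of tested genes, the naming rule) with separate groups were in Klf2 (log2 8.83 ± 1.25, SE; adjusted p = 3.04e-09), Tnf (8.30 ± 1.20; 8.38e-09), Fos (7.25 ± 1.33; 2.35e-05) and Spp1 (6.84 ± 1.10; 6.18e-07), followed by Dusp1, Fxyd5, Adamts1 and Egr2. Among the declines in the authors' deposited table under the same limit on the mean, the greatest were in Ogfod3, a prolyl hydroxylase-like protein (-2.15 ± 0.40, SE; adjusted p = 2.52e-05), Vps52, a subunit of a vesicle tethering complex (-2.03 ± 0.47; 0.00222), Carhsp1 (-1.98 ± 0.57; 0.0290) and Pigt, of the GPI anchor machinery (-1.75 ± 0.44; 0.00653), then Zdhhc24, Gpr107 and Thap4.

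In whole hippocampus, 18 months against 6 months, 3 of the 39 tested lists changed and no single gene passed over all genes. Globin mRNAs of red blood cells rose: Hba-a2, an alpha globin (chromosome 11, 32296489 to 32297298), went from 14.3 ± 5.52 to 90.5 ± 45.5 normalized counts (SD, n = 3 each; log2 change 2.49 ± 0.49, SE). Hba-a1 went from 6.60 ± 1.08 to 42.4 ± 14.6 (2.47 ± 0.59) and Hbb-bs, a beta globin, from 19.1 ± 8.11 to 72.5 ± 39.5 (1.79 ± 0.51). Of the 6 tested red blood cell markers 5 had a higher mean and 3 rose when adjusted over the list alone (median 1.53, camera adjusted p = 1.60e-04; adjusted p = 0.790 with an estimated correlation). Hba-a1 and Hba-a2 are near-identical copies, so the split between them is uncertain. Alas2, the haem synthesis enzyme of red cell precursors, was low at both ages (log2 change -0.77 ± 0.98, SE).

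Mitochondrially encoded mRNAs fell in the aged hippocampus. mt-Nd1, mt-Nd2 and mt-Nd5, subunits of respiratory complex I, had log2 changes of -0.63 ± 0.18, -0.53 ± 0.16 and -0.46 ± 0.15 (SE), with every 18 month library below every 6 month one. Of 13 such mRNAs 12 had a lower mean and 5 fell when adjusted over the list alone (median -0.37, adjusted p = 5.40e-06; adjusted p = 0.790 with an estimated correlation). They made up 6.44% to 7.87% of the signal at 6 months and 3.91%, 5.81% and 7.06% at 18 months. Cytosolic ribosomal proteins rose slightly (60 of 78 with a higher mean, 0 adjusted over the list alone, median 0.19, adjusted p = 1.60e-04; adjusted p = 0.790 with an estimated correlation), as for Rps29 (0.50 ± 0.21, SE) and Rpl27a (0.57 ± 0.25). That call was lost without 6 month replicate 2 (adjusted p = 0.106). Choroid plexus admixture varied widely: Ttr, the transthyretin of that tissue, ranged from 74.8 to 6590.3 normalized counts at 6 months and from 208.0 to 10458.1 at 18 months, and the choroid plexus list did not pass (adjusted p = 0.666) but passed as higher without 6 month replicate 2 (0.0144) or 18 month replicate 3 (0.00747).

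**Figure D3:**
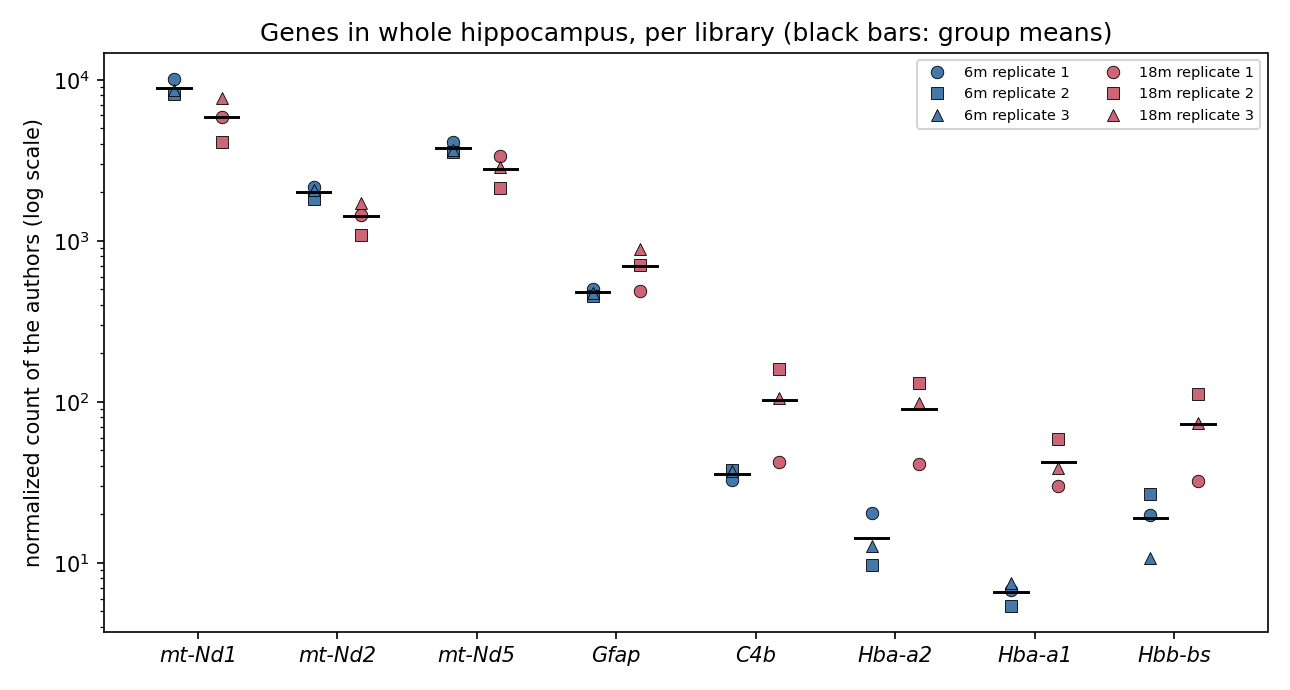
Normalized counts of the authors for 8 genes in the 6 whole-hippocampus libraries (y axis, log scale), with black bars at the mean of each age. The globin mRNAs Hba-a1, Hba-a2 and Hbb-bs are higher in each 18 month library than in any 6 month one (Hba-a2 41.4 to 131.2 against 9.65 to 20.4), and mt-Nd1 is lower in each.

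No list of glial or immune genes passed in the aged hippocampus with all 6 libraries. Complement component C4b, made by glia, stood at 35.8 ± 2.84 and 102.7 ± 59.0 normalized counts (SD, n = 3 each; log2 change 1.30 ± 0.42, SE), and Gfap, the intermediate filament of astrocytes, at 477.6 ± 23.8 and 694.4 ± 203.9 (0.50 ± 0.19). Apoe had a log2 change of 0.29 ± 0.12 (SE), against 2.21 ± 0.26 in microglia. The complement list did not pass (adjusted p = 0.101) but passed as higher without 6 month replicate 2 (0.0406) or 18 month replicate 3 (0.0193). The lists of homeostatic microglia (0.384), disease-associated microglia (0.697), immediate early genes (0.697), interferon genes (0.697), myelin genes (0.697) and adult neurogenesis genes (0.561) did not pass. Serpina3n (-0.42 ± 0.28, SE), Dcx (-0.60 ± 0.72), Neurod1 (-0.04 ± 0.36), C1qa (0.34 ± 0.28), Mbp (0.12 ± 0.12), Bdnf (0.50 ± 0.33), Arc (-0.32 ± 0.26), H2-K1 (0.50 ± 0.40), B2m (-0.14 ± 0.20), Ifit3 (0.38 ± 0.61), Trem2 (-0.16 ± 0.55), Cd68 (0.03 ± 0.63), Lgals3 (0.51 ± 1.01), Col1a1 (0.22 ± 1.01) and Cdkn1a (0.13 ± 0.64) lay within 2 errors of 0. Clec7a was listed at 6.66 normalized counts or less in every library and was not tested; Cst7 and Itgax were not analysed here.

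Gene by gene, limma called 0 of 13491 genes higher and 0 lower in the aged hippocampus, with a smallest adjusted p of 0.155. At an unadjusted p under 0.05 there were 288 genes higher and 437 lower, 725 together where 675 were due by chance. Limma without the mean trend called 0 higher and 1 lower. The authors' deposited table lists 14 genes higher and 22 lower at 18 months. By the authors' deposited table the rises with separate groups included Hba-a2 (log2 2.61 ± 0.46, SE; adjusted p = 3.64e-05), Hbb-bs (2.01 ± 0.48; 0.0199), Dkc1, a pseudouridine synthase (1.56 ± 0.34; 0.00381), and C4b (1.55 ± 0.39; 0.0316). Also higher in the authors' deposited table were Gjb6, a gap junction protein of astrocytes (1.18 ± 0.29; 0.0261), and Eif4g1, a scaffold of translation initiation (1.06 ± 0.22; 0.00247), with Tbc1d10b and Ubr4. The declines in the authors' deposited table included Nr3c1, the glucocorticoid receptor (-1.80 ± 0.34; 1.96e-04), Wdr7, a regulator of vesicle acidification (-1.50 ± 0.24; 1.86e-06), Dcc, the netrin receptor (-1.89 ± 0.50; 0.0482), and Disp2 (-0.95 ± 0.15; 1.86e-06), with Rfx3, Pgm2l1 and Kcnab2. Nr3c1 lay at 98.3 ± 16.1 and 28.0 ± 9.62 normalized counts at 6 and 18 months (SD, n = 3 each).

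The comparisons of the 2 tissues, which differ in age as well, shared no gene call in the same direction, and of the lists only cytosolic ribosomal proteins rose in both (camera, adjusted p = 0.00116 in microglia and 1.60e-04 in hippocampus). Both ribosomal calls were lost with an estimated correlation (adjusted p = 0.522 and 0.790). They were also lost without 3 month replicate 3 in microglia (0.317) and without 6 month replicate 2 in hippocampus (0.106). EdgeR and limma called 0 genes in either comparison, and of 9608 genes with an adjusted p in both of the authors' deposited tables, 0 were called higher in both (0.166 expected of independent lists) and 0 lower in both (0.0568 expected). Kcnab2, a potassium channel subunit, was called in both of the authors' deposited tables with opposite signs (log2 7.88, adjusted p = 0.00385 in microglia, and -0.74, adjusted p = 0.0259 in hippocampus). Kcnab2 was at 0 in the young microglia, so 7.88 is a fitted value. The floor of 3 counts over the young group gives at least 31.4-fold. At an unadjusted p under 0.05 in both comparisons there were 34 genes, of which 9 changed in the same direction. Across the 9770 genes tested in both, which are not independent replicates, the log2 changes had a Pearson r of -0.0509 and a Spearman rho of -0.0625. Mitochondrially encoded mRNAs rose in the microglia (change of the list score 1.68) and fell in the hippocampus (-0.33). Permuting ages within tissue (400 permutations) gave the difference an adjusted p of 0.128 over 32 lists. This was the smallest value of any list and was shared with 4 others, immediate early genes among them. So few permutations over 32 lists leave little room for an adjusted p under 0.05. These values therefore do not show that the tissues are alike.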

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

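The 5 genes below were picked out after the results were seen, because their groups did not overlap in either tissue in the values used here and their log2 changes had opposite signs; the difference between the tissues was not tested for any of them. Chance gives such opposite separation in 0.5% of genes chosen without regard to their result; many named genes were chosen by their result, so that share does not apply to them. Tmem119, the surface marker of resident microglia, had a log2 change of -0.54 ± 0.22 (SE, n = 3 per age) in microglia and 0.82 ± 0.40 in whole hippocampus. Its change in microglia was -0.81 without 24 month replicate 3, so that library fell less than the other old ones. mt-Nd5, the mitochondrially encoded subunit of complex I, had 3.67 ± 0.76 in microglia and -0.46 ± 0.15 in hippocampus, with 286.9, 439.7 and 59.3 CPM in the 3 old microglia libraries. Egr1, an immediate early transcription factor, had 7.34 ± 1.65 in microglia and -0.21 ± 0.18 in hippocampus; in 24 month replicate 3 it stood at 29.0 CPM, beside 28.8 CPM in 3 month replicate 1, and by the normalized counts of the authors' deposited table these libraries are in the reverse order (306.3 and 324.7), so the groups overlap there. Cenpf, a kinetochore protein of dividing cells, had 3.08 ± 1.33 in microglia and -1.84 ± 0.87 in hippocampus, where it was at 5.93 normalized counts or less. Kcnab2, a subunit of potassium channels and mainly neuronal, was at 0 in the young microglia and at 2.60 ± 0.525 CPM (SD, n = 3) in the old. That is at least 31.4-fold higher against a floor of 3 counts over the young group, where the fitted log2 change was 7.84 ± 1.36 (SE), against -0.75 ± 0.19 in hippocampus. The ages differ between the tissues as well (3 and 24 months, 6 and 18 months).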

How the results depend on the processing

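Of the 114 gene and list counts under alternative settings, 78 equalled the count they were set against or stayed within 1.5 times of it. That does not mean that the same genes or lists were called. Most of the 78 were counts of 0 set against 0. A stricter p or an added 2-fold minimum could not have raised a count of 0, so they say nothing on stability. For microglia, edgeR's 0 genes higher and 0 lower became 194 and 57 with the DESeq2 Wald test, 186 and 57 in the authors' deposited table, 186 and 56 there with a base mean of at least 10, and 186 and 57 with DESeq2 and gene lengths (chosen after seeing the data). Without 1 replicate the edgeR counts ranged from 0 to 50 higher and from 0 to 5 lower. DESeq2 with gene lengths and 1 replicate left out called 95 to 406 genes higher and 39 to 337 lower; it called 105 and 32 with replicate 1 of both ages left out, and 3 higher and 44 lower with 24m replicates 1 and 2 left out, library sets chosen after seeing the data. Of the 243 deposited calls, DESeq2's Wald test shared 209 and DESeq2 with gene lengths 243; the latter kept 90 to 203 of them without 1 replicate, 62 with replicate 1 of both ages left out and 4 with 24m replicates 1 and 2 left out. In the hippocampus, limma's 0 and 0 became 14 and 22 in the authors' deposited table, 14 and 19 with a base mean of at least 10, 1 lower without the trend, and 0 to 1 higher with 1 replicate left out. The 15 microglia lists became 0 with an estimated correlation, 2 with fry, 11 to 16 without 1 replicate and 5 with 24m replicates 1 and 2 left out. That setting leaves 1 old library, so all spread comes from the young ones and its calls are not read as kept or lost; the 5 include heat shock proteins as lower and cholesterol biosynthesis, which are not among the 15 as called. With replicate 1 of both ages left out, 12 lists were called. The 2 microglia lists called by fry were homeostatic genes (adjusted p = 0.0371) and interferon genes (0.0457). The 3 hippocampus lists became 0 with an estimated correlation, 0 with fry and 3 to 6 without 1 replicate; besides complement and choroid plexus genes, those gained were oligodendrocyte precursor markers as lower and neighbouring region markers as higher without 6m replicate 2 (adjusted p = 0.0144 each) and nuclear oxidative phosphorylation genes as higher without 6m replicate 1 (0.0157). With 24m replicates 1 and 2 left out, the lysosome median turned to 0.0872 and that of heat shock proteins to -0.23, and among named genes P2ry12 turned to -0.18, Cx3cr1 to 0.0145, Itgax to -0.29, Dnajb1 to -0.39, Junb to -0.0452 and Vim to -6.50. With replicate 1 of both ages left out, Cx3cr1 was at 0.0250 and Ifitm3 at 1.62. Without 1 replicate, P2ry12 ranged from -0.0509 to 0.10, Itgax from -0.0278 to 7.78 and Ifitm3 from -0.45 to 1.51. Ifitm3 was also at 0.0268 in the authors' deposited table, with or without a base mean of at least 10, 0.0627 with gene length offsets, 0.0267 with DESeq2 and gene lengths, 1.30 with limma-voom library quality weights and 0.0515 with 24m replicates 1 and 2 left out; it was at 52.1 CPM in 3 month replicate 1 and at 8.10 and 7.69 CPM in the other young libraries. In the hippocampus, the values without 1 replicate spanned 0 for Neurod1 (-0.19 to 0.15), Lgals3 (-0.39 to 1.06), Cd68 (-0.32 to 0.32), Col1a1 (-0.91 to 0.88), B2m (-0.21 to 0.0022), Trem2 (-0.35 to 0.12) and Cdkn1a (-0.24 to 0.42). The replicate number as a block left the gene counts at 0, the lists at 15 and 3 and Ifitm3 at 0.67; DESeq2 with gene lengths called 194 higher and 38 lower with this block and kept 120 of the 243 deposited calls. Samples of equal number correlated at 0.0849, 0.0304 and -0.0100 in microglia and 0.0117, 0.0094 and 0.0142 in hippocampus once age means were removed. Only number 1 of the microglia was its own best match. So few libraries cannot exclude that samples of equal number shared a batch. Of 1393 values of 82 named microglia results, 22 in 7 genes turned direction, as did 10 of 597 in 7 hippocampus genes; the cause was not tested.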

Other observations

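Some further genes, chosen after their values were seen, add to the picture of old microglia. Cd22, a sialic acid receptor of B cells that restrains phagocytosis in microglia, stood at 5.32 ± 5.13 CPM at 3 months and 51.2 ± 30.5 CPM at 24 months (SD, n = 3 each; log2 change 3.27 ± 1.03, SE). B cell markers summed to 1073.8 to 1396.5 CPM at 3 months and 901.9 to 1045.2 CPM at 24 months. H2-Aa, an MHC class II chain, was at 0.720 ± 0.340 and 9.47 ± 2.34 CPM (log2 change 3.70 ± 1.20, SE), beside the change of Cd74. The authors' deposited table, made with gene lengths, gives H2-Aa a log2 change of 5.32 ± 0.64 (SE), so its size depends on the processing. Bok, a relative of BCL2, was at 0 in the old libraries, at least 26.2-fold lower against a floor of 3 counts over the old group.

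Immediate early and cytokine genes were high in 24 month replicates 1 and 2. Stress while the tissue was taken apart could give this, as heat shock genes answer the same stress. Without the 3 genes shared with the immediate early list, the heat shock score (20 genes) was 0.51 and 0.43 in these libraries and -0.02 or lower in the other 4, a gap of 0.44, so the explanation stays possible; this form of the test was set after results were seen. RNA from neurons is unlikely, as pan-neuronal markers together reached 7.04% of Fos in 24 month replicate 1 and 4.56% in 24 month replicate 2. RNA from other cells seen in these libraries, such as neutrophils in 24 month replicate 1, was not tested as a source. Age itself may also differ in effect between mice, and 3 libraries cannot separate the possibilities.

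Apoe and other disease-associated genes were high in all 3 old libraries. The rise of Apoe did not follow border-associated macrophages: their 13 low-baseline markers of 14 rose by 0.554% of the rise of Apoe (2931.5 CPM), a test set after results were seen. These markers summed to 54.5 CPM in 24 month replicate 2 and to 2.49 to 11.6 CPM in the other libraries. Apoe was highest in 24 month replicate 3 (4880.9 CPM), where the markers were at 5.32 CPM, within the young range. How much Apoe these cells hold per marker is not known here, so a share from them cannot be excluded. Dissociation stress could act here too, but 24 month replicate 3, with few immediate early mRNAs, had 94.7% of the rise seen in 24 month replicates 1 and 2. As this is a single library and this test too was set after results were seen, the question stays open.

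Globin mRNAs were higher in the 18 month hippocampus. RNA from blood left in the tissue could give this, and alpha and beta globin would then keep their ratio. The log2 ratio of alpha to beta was 0.80 higher at 18 months, against an SD of 0.62 over libraries, and the ratios of the ages overlapped, so the test, set after results were seen, leaves the source open.

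The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. EdgeR called 0 microglia genes with the real split and at most 0 in the others, so 10 of 10 splits had as many. DESeq2 with gene lengths called 243 with the real split and 327 with 3 month replicate 1 and 24 month replicates 1 and 2 set against the rest, so 2 of 10 had as many. Microglia lists gave 15 with the real split and at most 9 in any other, so 1 of 10 had as many. Limma called 0 hippocampus genes with the real split and at most 0 in the others (10 of 10), and hippocampus lists gave 3 with the real split and up to 6 in others (4 of 10).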
